A study of Mus musculus with 21 samples.

How the data were processed

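The deposited values were log2 levels, 1 value per probe and array, for 21 arrays of epididymal fat. Per the labels' protocols, total RNA was extracted with Trizol, and sense cDNA was fragmented and labelled with biotin with a GeneChip whole-transcript kit. The summarisation, background correction and normalization by the authors are not given in the sources used here, nor is the log base. The base was taken from the values: they ran from 0.84 to 12.7, and the top exceeds what a natural or decimal log of a scanner signal can reach. Columns were matched to samples by name, and 0 array columns were left unmatched. Groups, and the numbers used here as mouse numbers, were taken from the titles and group labels.

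The table held 24292 probes, and its last row ended after 12 values, so 24291 probes with all 21 values were used. Probes ran in genome order. By the chromosomes of the reference table of genes (assembly GRCm38.p6, used for names and chromosomes only), between 78.1 and 91 percent of protein-coding genes were measured on chromosomes 1 to 5 and 10 to 19, 42 percent on chromosome 6, and 18 genes in all on chromosomes 7, 8, 9, X and Y. The table is thus held in part, and other genes were not analysed here. Counts of changed genes and of list members refer to the measured part. Probe names came from the platform annotation: 17067 of the complete probes had 1 gene symbol, 1139 several and 6085 none there. Probes with several or no symbols entered no gene test. Entrez identifiers of 116 probes had no match in the table of genes and kept their own symbol. For the 668 genes with more than 1 probe, the probe with the highest mean over all arrays stood for the gene, which left 16248 genes. Of 64 such genes called in HFD against ND, 20 had probes of both signs.

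No further normalization was applied in the main analysis. Each gene was fitted with limma 3.58.1 in R 4.3.3 with 1 coefficient per group over all 21 arrays, so that the groups share 1 estimate of the spread, and variances were moderated with an intensity trend. Contrasts were HFD against ND, each supplemented group against HFD, H_FMG against L_FMG, L_FMG against SMG and against BC, a trend linear in the percent of fermented grain (0, 0.3 and 0.9), and the mean of the 5 supplemented groups against HFD, and a moderated F test covered the 6 high-fat groups. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Comparisons with HFD share the same 3 HFD arrays. No scanning date or batch was given in the sources used here, so batches could not be checked.

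Of 37 gene lists, 36 had at least 4 measured members and were tested with camera (preset correlation 0.01), adjusted over the lists within each comparison. Of 485 distinct list genes 326 were measured, and 125 of the other 159 lie on chromosomes 6 to 9 or X. No list called with the preset correlation was called with a correlation estimated from the data, in any comparison, and the adjusted p with the estimated correlation stands beside the calls. Camera compares a list with the other genes. Fry tests whether a list's genes move on balance in 1 direction, and called 7 lists in HFD against ND and 0 in the other comparisons. For called lists the mean, the median and the test had the same sign. Counts of members adjusted over a called list alone describe that list. They come from the data that called it, so they are no separate support. Lists describe whole tissue: a marker list can move through the number of cells or through expression per cell.

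Genes named in the text follow a rule. The rule, the gene lists, the groups, the main tests and the alternatives, except those named as added, were fixed before the data were examined. It takes, in each comparison, the 10 largest rises and falls among genes past the threshold with non-overlapping arrays, without predicted gene models (non-overlap was not asked of the trend and the pooled comparison), the smallest p up to 5 per direction where fewer passed, up to 4 members with the smallest p from each called list, and a core panel of obesity markers. The text gives a selection of these.

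The position along the diet axis was the slope through the origin, over all genes, of a group minus HFD on the mean of the other 4 supplemented groups minus ND, with an exact permutation of 6 arrays. Genes are not independent replicates, so only the arrays were permuted.

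The gene test was tested on simulated values with the fitted spread of 16248 genes, of which 200 were changed. For HFD against ND it recovered 38.8, 97 and 100 percent of genes changed by 0.5, 1 and 1.5 log2 units, and called 8 unchanged genes. For H_FMG against HFD it recovered 29.9, 95.5 and 93.9 percent and called 10 unchanged genes. Of 10 simulated lists shifted by 0.5 all 10 were called, and 0 of 10 unshifted lists. The simulated genes were independent, which real genes are not. They also had the same spread in all groups, and the changed genes were drawn at random. In the data the spread differed between groups: positions along the diet axis had an SD of 0.309 in H_FMG and 0.134 in HFD. The shares recovered therefore need not hold for genes that vary more. A slope set to -0.5 came out as -0.47. In that simulation every gene had a diet effect and the other supplemented groups lay at the position of HFD. The real data need not be like this, so the recovery does not vouch for the slopes given here.

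Alternatives were quantile normalization, median centring, variances without a trend, fits of the compared groups alone, dim genes left out (below the median mean level), the mean of a gene's probes, every probe tested, array weights, the mouse number as a block, a threshold of 0.1, camera with an estimated correlation, fry, and each array left out in turn. Where this left 2 arrays in a group, the spread still came from all groups. Leaving ND array 9 out of comparisons without ND, and list tests after quantile normalization, were added after the data were seen.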

Results

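Gene expression was measured in the epididymal fat, the visceral fat pad beside the testis, of male C57BL/6J mice with GeneChip whole-transcript arrays. The mice were 4 weeks old on arrival, had 1 week of acclimation and were then fed their diets for 12 weeks. There were 21 arrays, 3 in each of 7 groups. For ND, HFD, BC and SMG 10 mice per group are stated, and how those for the arrays were chosen is not given in the sources used here. ND mice ate a normal diet with 10% of energy from fat, and HFD mice a high-fat diet with 40%. The other 5 groups were labelled with the high-fat diet and carried a supplement: BC received 0.3% by weight of Bacillus coagulans, a spore-forming bacterium used as a probiotic, SMG received 0.3% steamed grain, L_FMG received 0.3% fermented mixed grain and H_FMG received 0.9% fermented mixed grain. The fifth, RMG, is a code whose supplement and dose the protocols do not describe. Arrays are named here by group and the number in their title, taken as the mouse number, which reached 12 in SMG. The arrays of a group are treated as separate animals, which the single housing of the mice does not by itself establish. With 3 arrays per group, their number limits the precision. Values were log2 levels for 16248 genes. The table was held in part: genes of chromosomes 7, 8, 9 and X and of part of chromosome 6 were, with few exceptions, not analysed here. Array medians ran from 4.23 to 4.39 log2 units, and no pair of arrays held identical values.

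The study's title names dose-dependent effects of the fermented grain on adiposity under high-fat feeding, and the comparison of HFD with ND gives the effect of the diet itself. High-fat feeding raised genes of macrophages and of lipid-laden macrophages in the fat. Trem2, a lipid-sensing receptor of macrophages, rose by 2.08 ± 0.42 (log2 change ± SE, n = 3 against 3) and Gpnmb, a glycoprotein of lysosome-rich macrophages, by 2.23 ± 0.44, with adjusted p of 0.00564 and 0.00487. Tm4sf19 rose by 2.74 ± 0.45, Dhrs9, a dehydrogenase that acts on retinoids, by 2.62 ± 0.45, and Rgs1, a regulator of G-protein signalling in leukocytes, by 2.16 ± 0.43. The 10 largest rises under the naming rule also held Olfr111, Il7r, Atp6v0d2, Cpa3 and Myh15, and lay between 2.04 and 2.88. Orm3, an acute-phase plasma protein gene, fell by 1.83 ± 0.37, the largest fall (adjusted p = 0.00525). Serpina1d, a protease inhibitor gene, fell by 1.07 ± 0.21 and Rasd1, a small GTPase gene, by 1.08 ± 0.24. Pck1, whose enzyme supplies glycerol for triglyceride in adipocytes, fell by 1.07 ± 0.28, and Gpat3, an acyltransferase of triglyceride synthesis, fell by 1.02 ± 0.28. Rnase2a, Vmn1r3, Ctcflos and the small nucleolar RNA genes Snora47 and Snora73b completed the falls. Olfr111, Orm3, Serpina1d, Rnase2a and Vmn1r3 belong to families of closely similar genes, so the member that the probe reads is uncertain.

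In all, 1403 of 16248 genes passed in HFD against ND, 1063 higher and 340 lower in HFD (75.8% higher), by limma with Benjamini-Hochberg adjustment. The 3 HFD arrays lay wholly above or wholly below the 3 ND arrays in 28.7% of genes, where chance gives 10%. After quantile normalization 679 genes were higher and 447 lower, which is 60.3% higher, and 832 of the 1403 genes passed again. Without HFD array 6 the count was 368 and without HFD array 7 it was 826, and in a fit of the HFD and ND arrays alone it was 774. Of the 55 named genes that passed, 28 passed whichever single array was left out, among them Trem2, Gpnmb, Tm4sf19, Dhrs9, Rgs1, Orm3, Serpina1d and Rasd1. None of the 55 changed direction in any setting. After quantile normalization 8 of them lost the call, Vmn1r3, Rnase2a, Atf3, Pdgfra, Sdf2l1, Fn1, H2-Aa and Col1a1, and with the HFD and ND arrays alone Gpnmb (adjusted p = 0.0559), Atf3, Aurkb, Gpat3, Vmn1r3, Snora73b, Sqle, Acvr1c, Acaca and Fasn did. With every probe tested Rnase2a, Kif11, Cdk1 and Sqle lost it (adjusted p = 0.0511, 0.0514, 0.0531 and 0.0507). Without HFD array 6 the call was lost by 27 of the 55, among them Atf3, Cdk1, Aurkb, Sdf2l1, Fos and Hsd17b7 (adjusted p = 0.106, 0.185, 0.0941, 0.111, 0.0517 and 0.062), of which Atf3, Cdk1, Aurkb and Sdf2l1 also lost it without other single arrays. They also took in Cpa3, Pck1, Gpat3, Rnase2a, Vmn1r3, Ctcflos, Snora47 and Snora73b (adjusted p = 0.127, 0.133, 0.121, 0.13, 0.0976, 0.053, 0.0524 and 0.0866). Of these 8, Cpa3, Vmn1r3 and Snora73b also lost it without ND array 9 (0.0597, 0.155 and 0.164), Pck1, Gpat3 and Rnase2a without ND array 6 (0.0683, 0.0777 and 0.0604) or ND array 8 (0.0661, 0.101 and 0.153), Gpat3, Rnase2a, Vmn1r3 and Snora73b without HFD array 4 (0.0504, 0.0527, 0.0765 and 0.0647), and Cpa3, Gpat3, Rnase2a, Vmn1r3, Snora47 and Snora73b without HFD array 7 (0.0834, 0.0543, 0.118, 0.0829, 0.052 and 0.123).

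**Figure D1:**
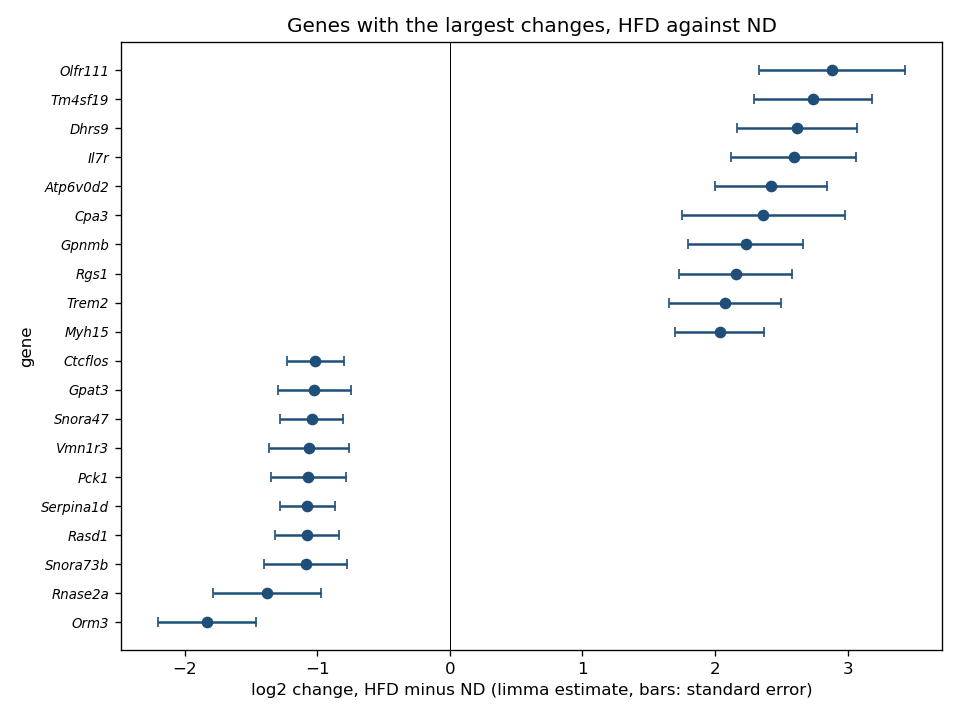
Log2 change of HFD minus ND (horizontal axis, log2 units) for the genes with the largest rises and falls among those past the threshold with non-overlapping arrays. Points are limma estimates for 3 against 3 arrays. Bars are their standard errors, from the moderated spread estimated over all 21 arrays. Rises reached 2.88 for Olfr111 and the largest fall was -1.83 for Orm3.

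Of 36 gene lists fixed beforehand, 12 differed between HFD and ND from the other genes (camera with a preset correlation). The balance changed with the processing: 9 of the 12 were higher in HFD, against 9 of 18 after quantile normalization and 5 of 11 with dim genes left out. With an estimated correlation, the adjusted p of all 12 lists lay between 0.334 and 0.41. The macrophage list was higher in HFD by a mean of 1.10 log2 units, with SDs between arrays of 0.11 in HFD and 0.29 in ND, and 12 of its 13 measured members rose, also 12 when adjusted over the list alone. Fcgr1, an immunoglobulin receptor, rose by 1.99 ± 0.31, Ms4a7 by 1.92 ± 0.32, Cd68, a lysosomal glycoprotein, by 1.60 ± 0.29 and C1qb, a complement component, by 1.29 ± 0.26. The lipid-associated macrophage list was higher by a mean of 1.41, and 8 of its 9 members rose, likewise 8 when adjusted over the list alone, among them the protease gene Ctsk by 2.01 ± 0.37, the lysosomal lipase gene Lipa by 1.23 ± 0.23 and the galectin gene Lgals3 by 0.97 ± 0.18. In ND array 9 this list stood at -0.655 relative to the HFD mean, against -1.67 and -1.91 in ND arrays 6 and 8.

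Connective tissue and proliferation genes were also higher in HFD as lists, though with an estimated correlation no adjusted p of these lists was below 0.334. In the extracellular matrix list, with a mean change of 0.44, 6 of 16 members rose (9 when adjusted over the list alone), among them Lum, a matrix proteoglycan gene, by 1.40 ± 0.26, Mmp14, a membrane-bound matrix protease gene, by 0.98 ± 0.16, and the collagen gene Col1a2 by 0.67 ± 0.14. In the cell cycle list, with a mean change of 0.58, 4 of 15 members rose (7 adjusted over the list alone), among them the mitotic genes Kif11, by 0.99 ± 0.29, and Tpx2, by 0.95 ± 0.27. In the cholesterol synthesis list 3 of 11 members rose (6 adjusted over the list alone), among them Srebf2, its master regulator, by 0.64 ± 0.13 and the epoxidase gene Sqle by 0.64 ± 0.19. Members also rose in the unfolded protein list (2 of 10, 5 adjusted over the list alone), the immediate early list (3 of 10, with Egr2 at 1.63 ± 0.33, and 5 adjusted over the list alone), the MHC class II list (1 of 6, H2-Aa, and 2 adjusted over the list alone) and the fibroblast and progenitor list (1 of 8, Pdgfra, also 1 adjusted over the list alone). The unfolded protein list missed the threshold after quantile normalization (adjusted p = 0.0906), the fibroblast list without ND array 9 (adjusted p = 0.0753) and the immediate early list without ND array 8 (adjusted p = 0.0551). With dim genes left out the unfolded protein, immediate early, MHC class II and fibroblast lists missed it (adjusted p = 0.0841, 0.132, 0.103 and 0.113). Among the genes named here, Col1a2, Kif11, Tpx2, Sqle, H2-Aa and Pdgfra lost the call without HFD array 6 (adjusted p = 0.0525, 0.164, 0.142, 0.209, 0.0839 and 0.0529), Kif11, Tpx2, Sqle and H2-Aa also without ND array 8 (0.0874, 0.0727, 0.116 and 0.0656), ND array 9 (0.0639, 0.0531, 0.0591 and 0.0756) or HFD array 7 (0.103, 0.081, 0.0814 and 0.0885), Kif11 and Tpx2 without ND array 6 (0.0677 and 0.0654), and H2-Aa without HFD array 4 (0.0836).

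Adipocyte, endothelial and lipolysis lists were lower in HFD, though with an estimated correlation their adjusted p was at least 0.334. Of the 7 lists that fry called in this comparison 6 were higher in HFD, so most of these lower lists were not called by fry. The adipocyte list had a mean change of -0.46, with SDs of 0.18 in HFD and 0.32 in ND, and 3 of 9 members fell (4 adjusted over the list alone). These were Pck1, Rbp4, a retinol carrier secreted by fat, which fell by 0.62 ± 0.16, and Acvr1c, a TGF-beta family receptor gene of adipocytes, which fell by 0.85 ± 0.23. In the endothelial list, with a mean change of -0.40, Vwf, the von Willebrand factor gene, fell by 0.71 ± 0.12 and was the 1 of 10 members that passed over all genes, against 7 adjusted over the list alone. In the lipolysis list 2 of 5 members fell, likewise 2 adjusted over the list alone. G0s2, an inhibitor of the adipose triglyceride lipase, fell by 0.88 ± 0.20. As the list holds this inhibitor, its shift does not give the direction of lipolysis. The lipolysis call was lost without ND array 6 (adjusted p = 0.0813) or ND array 8 (adjusted p = 0.0683), and in ND array 9 the adipocyte list stood 0.092 above the HFD mean, against 0.647 and 0.643 in ND arrays 6 and 8. Without HFD array 6, Rbp4, Acvr1c and G0s2 lost the call (adjusted p = 0.11, 0.108 and 0.0545), Rbp4 and Acvr1c also without ND array 8 (0.0578 and 0.103), and Acvr1c without ND array 6, HFD array 4 or HFD array 7 (0.0951, 0.0738 and 0.0519).

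Among 26 measured genes of a core panel of obesity markers, 8 rose and 2 fell in HFD, and 8 and 3 when adjusted over the list alone. The macrophage marker Adgre1 rose by 1.51 ± 0.32, the chemokine gene Ccl2 by 1.28 ± 0.25, the cytokine gene Tnf by 0.79 ± 0.21, Col1a1 by 0.66 ± 0.17, and Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, by 0.46 ± 0.10. The fatty acid synthesis genes Acaca and Fasn fell by 0.83 ± 0.21 and 0.57 ± 0.13. Leptin, Lep, had a log2 change of 0.42 ± 0.18 (adjusted p = 0.152), adiponectin, Adipoq, of -0.335 ± 0.17 (adjusted p = 0.236), Pparg of -0.31 ± 0.12 (adjusted p = 0.114) and the insulin-responsive glucose transporter Slc2a4 of -0.49 ± 0.22 (adjusted p = 0.156), and none of these passed. The panel as a whole did not pass against the other genes (adjusted p = 0.168). Tnf, Col1a1, Acaca and Fasn lost the call without HFD array 6 (adjusted p = 0.124, 0.112, 0.0718 and 0.0595) or ND array 8 (0.0712, 0.0561, 0.0726 and 0.0531), Tnf and Col1a1 without HFD array 4 (0.0505 and 0.0522), Col1a1 and Acaca without ND array 6 (0.0619 and 0.0692), and Col1a1 after quantile normalization (0.0694).

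**Figure D2:**
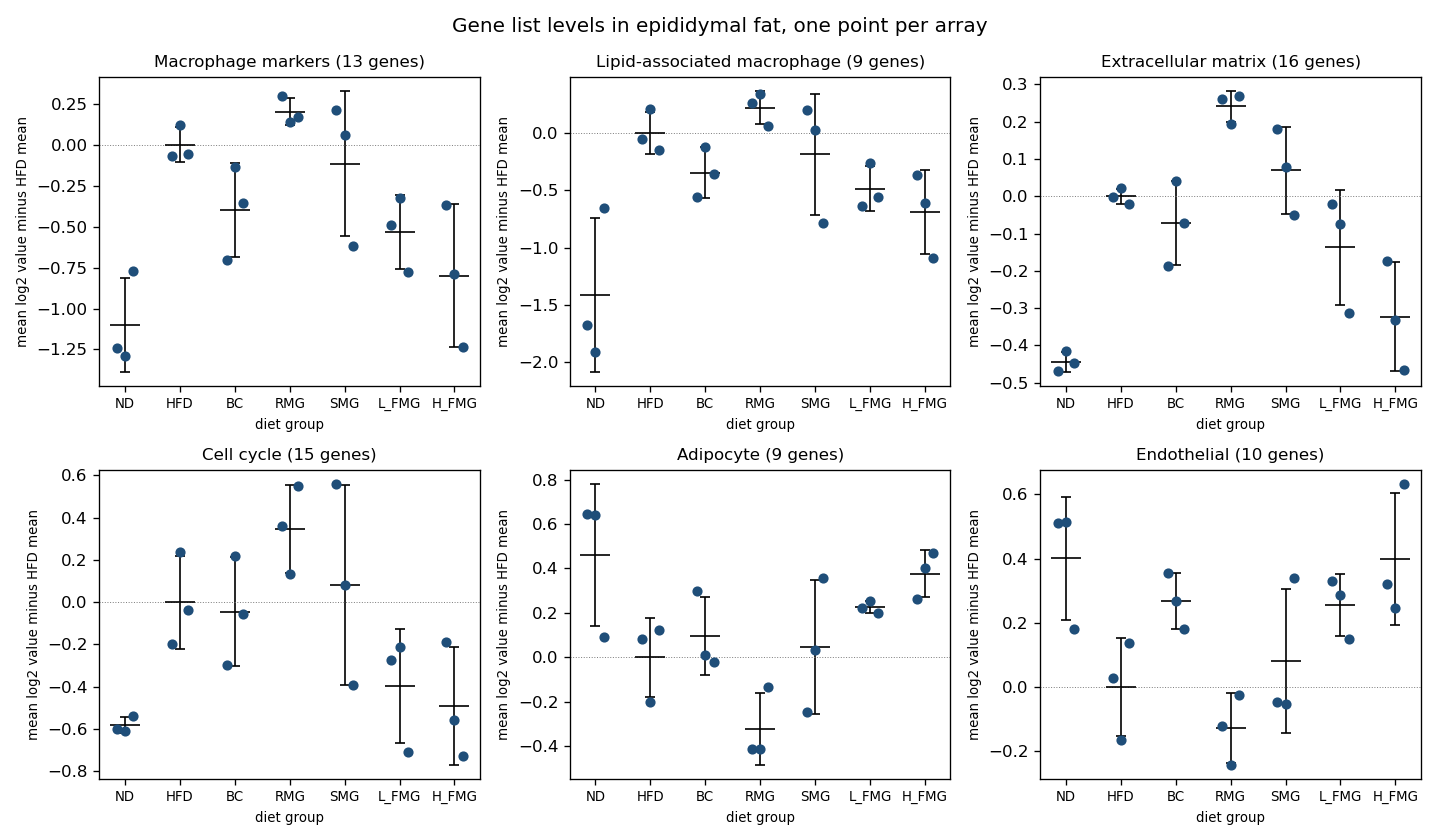
Mean log2 value of 6 gene lists in each array minus the mean of the HFD arrays (vertical axis, log2 units), by diet group (horizontal axis). Points are arrays, horizontal marks are group means and bars are SDs of 3 arrays. Macrophage genes lay between -1.29 and -0.77 in ND and between -1.24 and -0.37 in H_FMG.

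At the higher dose of fermented grain, H_FMG against HFD, macrophage and matrix genes were lower and adipocyte and endothelial genes higher as lists, while 1 single gene passed. With an estimated correlation each of the 15 called lists had an adjusted p of 0.317, and fry called 0 lists. The macrophage list had a mean log2 change of -0.80, with SDs between arrays of 0.44 in H_FMG and 0.11 in HFD. None of its 13 members passed over all genes, and 11 fell when adjusted over the list alone. Ms4a7 had a change of -1.48 ± 0.32 (adjusted p over all genes 0.0923), Fcgr1 of -1.21 ± 0.31 (adjusted p = 0.13) and C1qa of -0.90 ± 0.22 (adjusted p = 0.128). Lipid-associated macrophage genes had a mean change of -0.69, with 7 of 9 lower when adjusted over the list alone, among them Ctsk at -1.18 ± 0.37. Extracellular matrix genes had a mean change of -0.32, with 7 of 16 lower when adjusted over the list alone, among them Lum at -1.08 ± 0.26 and Mmp14 at -0.65 ± 0.16. The mast cell list had a mean change of -0.60, with 3 of 9 lower when adjusted over the list alone, and its protease gene Mcpt4 had a change of -1.69 ± 0.43. The endothelial list had a mean change of 0.40, with 9 of 10 members higher when adjusted over the list alone, Kdr, a VEGF receptor gene, at 0.56 ± 0.19. The adipocyte list had a mean change of 0.38 and the lipolysis list of 0.41, each with 1 member higher when adjusted over the list alone. Pck1 stood at 1.01 ± 0.28 and G0s2, the lipase inhibitor, at 0.75 ± 0.20, so the lipolysis list does not give the direction of lipolysis.

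In all, 15 lists were called in H_FMG against HFD, 3 up and 12 down, which also took in the cell cycle (mean change -0.49, 6 of 15 lower when adjusted over the list alone), cholesterol synthesis (-0.28), unfolded protein (-0.26), interferon (-0.21), MHC class II (-0.31), fibroblast and progenitor (-0.31), inflammatory cytokine (-0.29) and immediate early (-0.31) lists. When adjusted over the list alone, 3 cholesterol synthesis, 3 unfolded protein and 1 interferon gene were lower, and 0 members of the MHC class II, fibroblast, cytokine and immediate early lists passed. The immediate early call was lost after quantile normalization (adjusted p = 0.149) and without HFD array 7, H_FMG array 6 or H_FMG array 8 (adjusted p = 0.0841, 0.319 and 0.0736), and the cytokine call without H_FMG array 8 (adjusted p = 0.0793). With dim genes left out the fibroblast, immediate early, cytokine, interferon and MHC class II calls were lost (adjusted p = 0.0716, 0.231, 0.0732, 0.0732 and 0.0716). The balance of directions changed with the scaling and the genes tested: 6 of 17 called lists were up after quantile normalization and 5 of 11 with dim genes left out. The mean change was -0.182 for cholesterol synthesis without HFD array 6, -0.476 for immediate early genes without H_FMG array 3, and -0.204 and -0.196 for the fibroblast and MHC class II lists without H_FMG array 8. The SD of values over probes was 1.981, 1.917 and 1.905 in the H_FMG arrays, 1.977, 1.988 and 2.001 in the HFD arrays and 1.936, 1.921 and 1.823 in the ND arrays.

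Of single genes, Acr (probe 17314222), which encodes the sperm protease acrosin, rose in H_FMG by 0.66 ± 0.10 (adjusted p = 0.0342), from 5.07 ± 0.16 (SD) in HFD to 5.73 ± 0.08 in H_FMG. It was the 1 gene of 16248 past the threshold, against 2350 at an unadjusted p under 0.05. Amy2b at 1.13 ± 0.21, the angiogenic factor gene Vegfa at 0.89 ± 0.17, the interferon-inducible Ifi204 at -1.01 ± 0.20, Ms4a4a at -0.92 ± 0.19 and Oasl2 at -0.63 ± 0.12 were among the genes that came next, each with an adjusted p of 0.0816. The call on Acr was lost without any 1 of HFD arrays 4, 6 and 7 or of H_FMG arrays 6 and 8 (adjusted p = 0.0522, 0.18, 0.101, 0.0809 and 0.401), when the count was 0. It was also lost with every probe tested (0.0578) and with the H_FMG and HFD arrays alone (0.074), where 1 gene, not Acr, passed. Without H_FMG array 3 the count was 257, and with array weights, which favour arrays close to their group, it was 566.

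At the lower dose, L_FMG against HFD, 9 lists were called, and with an estimated correlation all 9 had an adjusted p of 0.847. The macrophage list had a mean change of -0.53, with SDs of 0.23 in L_FMG and 0.11 in HFD, and 8 of 13 members were lower when adjusted over the list alone, among them Ms4a7 at -0.98 ± 0.32 and C1qc at -0.76 ± 0.25. The lipid-associated macrophage list had a mean change of -0.49, the cell cycle list of -0.40 and the cholesterol synthesis list of -0.35, with 0, 0 and 5 members lower when adjusted over the list alone. In the last of these Lss, the lanosterol synthase gene, stood at -0.74 ± 0.23 and Cyp51 at -0.67 ± 0.22. The endothelial, adipocyte and lipolysis lists had mean changes of 0.26, 0.23 and 0.275. When adjusted over the list alone, 0, 1 and 1 of their members were higher. Pck1 of the adipocyte list stood at 0.88 ± 0.28, and G0s2, the lipase inhibitor of the lipolysis list, at 0.78 ± 0.20. The matrix list (-0.14) and the MHC class II list (-0.21) completed the 9 called lists, and both missed the threshold after quantile normalization (adjusted p = 0.676 and 0.276), with dim genes left out (0.347 for each), with array weights (0.228 for each) and without L_FMG array 10 (adjusted p = 0.834 and 0.437), HFD array 4 (0.107 and 0.14) or ND array 9 (0.0509 and 0.0505), the matrix list without HFD array 6 (0.0752) and the MHC class II list without HFD array 7 (0.0873) or L_FMG array 4 (0.119). In both, 0 members passed when adjusted over the list alone. No gene passed by limma (0 of 16248), with 1407 at an unadjusted p under 0.05. The small nucleolar RNA gene Snord104 came nearest, at 0.82 ± 0.13 (adjusted p = 0.087), followed by S100a5 at -0.81 ± 0.16 (adjusted p = 0.374). Ly96, the partner of the endotoxin receptor, had a change of -1.03 ± 0.22 (adjusted p = 0.454). The adipocyte and lipolysis calls were each lost without HFD array 6 (adjusted p = 0.376 and 0.169) and without L_FMG array 4 (adjusted p = 0.095 and 0.0982) or L_FMG array 8 (adjusted p = 0.12 and 0.0535), and without HFD array 6 the called lists numbered 6. Without L_FMG array 10 the cell cycle and cholesterol synthesis changes were -0.243 and -0.227.

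The dose question was put in a trend over HFD, L_FMG and H_FMG and in a direct comparison of the doses. The trend was in log2 units per percent of fermented grain in the diet. L_FMG, close to the mean dose, had the smallest weight in it, so the trend largely repeats H_FMG against HFD. It does not by itself show a graded response. The cholesterol synthesis list, called in the trend, had a mean change of -0.351 in L_FMG and -0.281 in H_FMG against HFD. In the trend 15 lists were called, with adjusted p of 0.284 to 0.407 with an estimated correlation. The macrophage list had a mean trend of -0.82 per percent, the lipid-associated macrophage list of -0.71, the matrix list of -0.35 and the mast cell list of -0.63, and the endothelial, adipocyte and lipolysis lists had trends of 0.415, 0.395 and 0.42. When adjusted over the list alone, 11, 7, 7 and 2 members of the first 4 lists had a negative trend and 8, 1 and 1 of the last 3 a positive one. Limma called 0 genes for the trend, with 2115 at an unadjusted p under 0.05, and Acr had the smallest p, at 0.69 ± 0.11 per percent (adjusted p = 0.0664). The cholesterol synthesis, immediate early, cytokine and MHC class II lists were called too, and without H_FMG array 8 they missed the threshold (adjusted p = 0.0608, 0.0608, 0.0797 and 0.0608), as cholesterol synthesis did without HFD array 6 (0.059) and immediate early without HFD array 7 (0.0579) or H_FMG array 6 (0.341) and after quantile normalization (0.0978). With dim genes left out all 4 missed it too (0.0852, 0.179, 0.0561 and 0.0666). Without H_FMG array 3 the immediate early and MHC class II trends were -0.53 and -0.482, and without H_FMG array 8 the lipid-associated macrophage trend was -0.47. Without L_FMG array 8 the count of genes was 1. Without H_FMG array 3 the trend count was 89, and with array weights 222.

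Between the doses, H_FMG against L_FMG, 8 lists were called, with adjusted p of 0.364 to 0.739 with an estimated correlation. The interferon list had a mean difference of -0.26, with SDs of 0.10 and 0.16, a negative sign in 11 of 12 members and 1 member lower when adjusted over the list alone. Oasl2, an interferon-induced gene, had a change of -0.43 ± 0.12 and Mx2 of -0.43 ± 0.18. The mesothelial list, markers of the sheet of cells that covers the fat pad, had a mean difference of -0.45, with Upk1b at -0.79 ± 0.47. The macrophage (-0.27), matrix (-0.19), fibroblast (-0.23), mast cell (-0.27) and unfolded protein (-0.12) lists were also lower and the endothelial list (0.14) higher, 8 lists in all. When adjusted over the list alone, 1 unfolded protein gene was lower and 0 members of the remaining 6 lists passed. By limma 0 genes passed, with 636 at an unadjusted p under 0.05. Without H_FMG array 8 the number of called lists was 4 and without L_FMG array 8 it was 5, and the macrophage difference was then -0.05 (adjusted p = 0.523) and -0.17 (adjusted p = 0.0775). Without H_FMG array 3 the called lists numbered 13. The mesothelial call was lost without H_FMG array 3 or L_FMG array 10 (adjusted p = 0.0708 and 0.0654), the endothelial call without L_FMG array 10 or H_FMG array 8 (0.292 and 0.895), the fibroblast and mast cell calls without L_FMG array 4 (0.0565 for each) or H_FMG array 8 (0.143 and 0.107), the mast cell call without L_FMG array 8 (0.0775), and the unfolded protein call without L_FMG array 8 or H_FMG array 8 (0.393 and 0.39). With array weights the mesothelial difference was -0.253 (0.141) and the endothelial difference 0.0884 (0.183). Calls that were kept moved too: the mesothelial difference was -0.683 without L_FMG array 8, mast cell -0.402 without L_FMG array 10, macrophage, fibroblast and unfolded protein -0.482, -0.354 and -0.193 without H_FMG array 3, endothelial 0.22 without H_FMG array 6 and matrix -0.116 without H_FMG array 8.

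In BC, the bacterium alone, against HFD, 5 lists were called, with adjusted p of 0.655 to 0.692 with an estimated correlation. The macrophage list had a mean change of -0.40, with SDs of 0.29 in BC and 0.11 in HFD, and all 13 members had a negative sign, with Fcgr1 at -0.62 ± 0.31 and C1qc at -0.49 ± 0.25. The MHC class II list had a mean change of -0.31, with all 6 members negative and H2-Ab1, a class II beta chain gene, at -0.37 ± 0.15. The immediate early list (-0.29) and the lipid-associated macrophage list (-0.35) were also lower, and the endothelial list was higher at 0.27, with Pecam1 at 0.39 ± 0.11. No member passed when adjusted over the list alone, except 3 endothelial genes. In limma's test 0 genes passed, with 841 at an unadjusted p under 0.05, and Clec4a4, a lectin receptor gene of myeloid cells, had the smallest p at -0.79 ± 0.14 (adjusted p = 0.363). The lipid-associated macrophage call was lost without HFD array 6 (adjusted p = 0.181) or BC array 4 (adjusted p = 0.222). Without BC array 4 the macrophage change was -0.244 (adjusted p = 0.0128). Without BC array 11 the number of called lists was 9, as it also was after quantile normalization.

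In SMG, the steamed grain, against HFD, 0 of 36 lists were called and 0 genes passed by limma, with 300 genes at an unadjusted p under 0.05. S100a5 had a change of -0.70 ± 0.16 and Hrk, a pro-apoptotic gene, of 0.48 ± 0.12, each with an adjusted p of 1. The SMG arrays differed among themselves: the macrophage list stood 0.212 and 0.06 above the HFD mean in SMG arrays 5 and 8 and at -0.62 in SMG array 12. Without SMG array 5, 1 gene and 5 lists were called, and without SMG array 12, HFD array 6 or HFD array 7 the lists called were 2, 2 and 1.

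In RMG against HFD, matrix, proliferation and macrophage genes were higher and adipocyte genes lower as lists. With an estimated correlation the 14 called lists had adjusted p of 0.24 to 0.638, and fry called 0 lists. The matrix list had a mean change of 0.24, with SDs of 0.04 in RMG and 0.02 in HFD, and 14 of 16 members were positive, with Postn at 0.35 ± 0.13 and Col5a2 at 0.34 ± 0.12. The cell cycle list had a mean change of 0.35, with all 15 members positive and Rrm2, a ribonucleotide reductase gene, at 0.50 ± 0.20. The adipocyte list had a mean change of -0.32, with all 9 members negative, and the branched-chain amino acid catabolism list of -0.25, with Hibch at -0.42 ± 0.15. Markers of the epididymis, the duct that lies against this fat pad, were higher by a mean of 0.22, and 2 of 15 passed when adjusted over the list alone, Gpx5 at 1.14 ± 0.26 and Defb20 at 0.72 ± 0.19, from HFD levels of 2.09 and 2.59, below the median level of 4.73 over all genes. A level of the epididymis list above HFD was not particular to RMG. Relative to the HFD mean it stood at 0.112, 0.362 and 0.196 in the RMG arrays. It stood at 0.098, 0.351 and 0.121 in the ND arrays and at 0.073, 0.247 and 0.113 in the H_FMG arrays. In the other called lists no member passed when adjusted over the list alone. The macrophage (0.20), lipid-associated macrophage (0.22) and cytokine (0.165) lists were also up, and the adipose expansion (-0.18), endothelial (-0.13), fatty acid oxidation (-0.10), insulin and glucose (-0.18), lipolysis (-0.19) and smooth muscle (-0.18) lists down, 14 lists in all.

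In RMG against HFD 0 genes passed by limma, with 458 at an unadjusted p under 0.05, and Lin28a had the smallest p at 0.65 ± 0.12 (adjusted p = 0.338). Without RMG array 9 there were 9 called lists, and the epididymis list had a mean change of 0.15 (adjusted p = 0.0783), and without HFD array 7 there were also 9. The endothelial, insulin and glucose, lipid-associated macrophage, lipolysis and smooth muscle calls were lost in both of these fits (adjusted p = 0.358, 0.153, 0.181, 0.14 and 0.0547 without RMG array 9, and 0.316, 0.118, 0.195, 0.0669 and 0.146 without HFD array 7). Fatty acid oxidation was lost without RMG array 9 (0.0859) or HFD array 6 (0.0701), cytokines without HFD array 7, HFD array 4, RMG array 4 or RMG array 10 (0.0669, 0.0929, 0.15 and 0.0706), and the macrophage, lipid-associated macrophage and insulin lists without HFD array 4 (0.0629, 0.154 and 0.0686) or RMG array 4 (0.15, 0.15 and 0.144). The endothelial change was -0.21 without HFD array 6, and the insulin and glucose change -0.27 without RMG array 10. In RMG array 9 the testis list stood 1.01 above the HFD mean, against 0.345 in the next highest array, BC array 11.

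Fermented grain at 0.3% was set against the other additions at 0.3%. Against steamed grain, L_FMG had lower cell cycle genes (mean -0.48, with SDs of 0.27 in L_FMG and 0.48 in SMG), lower macrophage genes (-0.42), lower cholesterol synthesis genes (-0.34), lower matrix (-0.21) and lipid-associated macrophage genes (-0.30), and higher endothelial (0.17), adipocyte (0.18) and mesothelial genes (0.325). These 8 lists had no member past the threshold when adjusted over the list alone and adjusted p of 0.444 to 0.791 with an estimated correlation. Top2a, a topoisomerase gene of dividing cells, had a change of -0.78 ± 0.26 and the histone gene H2bc12 of -1.04 ± 0.20 (adjusted p = 0.367). Limma called 0 genes, with 886 at an unadjusted p under 0.05, and with array weights 15. Without SMG array 5 the called lists numbered 4, and without L_FMG array 4 or L_FMG array 10 they numbered 5. The mesothelial call was lost in these 3 fits (adjusted p = 0.139, 0.204 and 0.179), as was the lipid-associated macrophage call (0.42, 0.197 and 0.0782), which also missed the threshold without SMG array 8 (0.167) and after quantile normalization (0.0809). The adipocyte call was lost without SMG array 5, SMG array 8, L_FMG array 4 or L_FMG array 8 (0.76, 0.0771, 0.111 and 0.128), the endothelial call without SMG array 5, SMG array 8 or L_FMG array 4 (0.176, 0.122 and 0.111), and the matrix call without L_FMG array 10 (0.0512). With array weights the mesothelial difference was 0.148 (0.351), and with dim genes left out the mesothelial and lipid-associated macrophage calls were lost (0.0885 and 0.121). Without SMG array 5 the cell cycle and macrophage differences were -0.242 and -0.252. Without SMG array 12 the macrophage, lipid-associated macrophage, endothelial and adipocyte differences were -0.668, -0.599, 0.304 and 0.334. The mesothelial difference was 0.554 without L_FMG array 8, and cholesterol synthesis -0.215 without L_FMG array 10.

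Against the bacterium, L_FMG had lower cell cycle (mean -0.35), cholesterol synthesis (-0.31), lipogenesis (-0.21), fatty acid oxidation (-0.12) and respiratory chain genes (-0.11) and higher interferon (0.145) and immediate early genes (0.135), with SDs of the cell cycle score of 0.27 in L_FMG and 0.26 in BC. These 7 lists each had an adjusted p of 0.827 with an estimated correlation. In the cholesterol synthesis list 3 of 11 members were lower when adjusted over the list alone, with Insig1, a sterol-sensing regulator gene, at -0.67 ± 0.20, in the cell cycle list 1 of 15 was, and in the lipogenesis list 2 of 15, among them the elongase gene Elovl3 at -1.32 ± 0.35. By limma 0 genes passed, with 666 at an unadjusted p under 0.05. Rxfp2, a relaxin family receptor gene, had the smallest p at -0.97 ± 0.18 (adjusted p = 0.3). The lipogenesis, oxidation and respiratory chain calls were each lost without L_FMG array 10 (adjusted p = 0.394, 0.481 and 0.481) and without BC array 4 (adjusted p = 0.073, 0.172 and 0.219), the respiratory chain also without L_FMG array 8 (0.053). The interferon call was lost without BC array 7, L_FMG array 4 or L_FMG array 8 (0.109, 0.15 and 0.177) and the immediate early call without BC array 4, BC array 11 or L_FMG array 4 (0.204, 0.0892 and 0.419). With array weights the immediate early call was lost (0.0657), and with the mean of a gene's probes the respiratory chain call (0.0551). The cell cycle difference was -0.221 without BC array 7 and -0.197 without L_FMG array 10. Immediate early genes stood at 0.211 without BC array 7, lipogenesis at -0.323 without L_FMG array 4, and cholesterol synthesis and interferon genes at -0.183 and 0.238 without L_FMG array 10. In a fit without ND array 9, 1 gene passed.

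Across all 5 supplemented groups, their mean against HFD gave lower macrophage genes (mean -0.33), lipid-associated macrophage (-0.30), MHC class II (-0.18) and cholesterol synthesis genes (-0.12) and higher endothelial genes (0.175), with adjusted p of 0.892 to 0.909 with an estimated correlation. No member of these 5 lists passed when adjusted over the list alone. By limma 0 genes passed, with 708 at an unadjusted p under 0.05. The cholesterol synthesis, endothelial and lipid-associated macrophage calls were lost without HFD array 6 (adjusted p = 0.811, 0.126 and 0.151), and the number of called lists was then 3, and it was 8 without SMG array 5. The MHC class II call was lost without HFD array 4 (0.0697), and the cholesterol synthesis call without ND array 9 (0.0562), HFD array 7 (0.0505), RMG array 9 (0.0697), SMG array 12 (0.06), L_FMG array 10 (0.0838), H_FMG array 6 (0.0577) or H_FMG array 8 (0.0595), and after quantile normalization (0.103) or with array weights (0.0854). With dim genes left out the cholesterol synthesis and MHC class II calls were lost (0.207 and 0.0503). Without HFD array 4 the cholesterol synthesis change was -0.198. The 5 groups did not all move the same way. In RMG against HFD the lipid-associated macrophage list stood at 0.22 and the endothelial list at -0.128, and the macrophage list was also higher.

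In a test for any difference among the 6 high-fat groups, 8 genes passed by limma's moderated F test, with 1976 at an unadjusted p under 0.05. The naming rule does not cover this test, so these genes were named after their values were seen: Vegfa, Mcoln2, H2bc12, Foxm1, Mfap5, Snord104, Shank3 and Tspan2. Vegfa was at 8.21 ± 0.22 (SD, n = 3) in HFD, 7.81 ± 0.16 in RMG, 8.86 ± 0.24 in L_FMG and 9.10 ± 0.32 in H_FMG (adjusted p = 0.0399). Foxm1, a transcription factor gene of dividing cells, was at 4.43 ± 0.04 in HFD, 4.81 ± 0.07 in RMG, 3.90 ± 0.14 in L_FMG and 4.14 ± 0.09 in H_FMG (adjusted p = 0.0443). Mfap5, a microfibril gene, was at 9.22 ± 0.16 in HFD, 9.56 ± 0.12 in RMG and 8.49 ± 0.35 in H_FMG (adjusted p = 0.0443). The count was 0 without any 1 of 12 of the arrays, all 3 of HFD and of RMG among them, 1 without L_FMG array 4, 23 without BC array 7, 67 without SMG array 5, 657 without SMG array 12, 150 without H_FMG array 3 and 242 without ND array 9. It was 56 after quantile normalization, 63 with dim genes left out, 1436 with array weights and 0 without an intensity trend in the variance.

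Each supplemented group was placed along the diet axis, the difference between the other supplemented groups and ND, where a slope of 0 means the position of HFD and -1 a shift by the whole length of the axis towards ND. The 2 sides of each slope share no array. The axis thus differs for each group, so the slopes are not on 1 scale. Genes that differed between the other supplemented groups and ND numbered 1349 on the H_FMG axis and 11 on the RMG axis. With such genes alone the slopes were -0.663 for H_FMG, -0.474 for L_FMG, -0.371 for BC, -0.14 for SMG and 0.21 for RMG. H_FMG had a slope of -0.59 (SD of its 3 arrays 0.31, of the 3 HFD arrays 0.13), L_FMG of -0.42 (SD 0.27), BC of -0.31 (SD 0.20), SMG of -0.10 (SD 0.36) and RMG of 0.16 (SD 0.14). In an exact permutation test, two-sided, over the 20 assignments of 6 arrays, H_FMG, L_FMG and BC each reached p = 0.1, the smallest that 3 against 3 arrays allow, so this design cannot pass 0.05 (adjusted p = 0.167 over 5 groups). RMG had an exact p of 0.2 and SMG of 0.9, with adjusted p of 0.25 and 0.9. All 3 arrays of H_FMG, of L_FMG and of BC lay nearer to ND than all 3 HFD arrays. The L_FMG slope was -0.267 without L_FMG array 10 and the BC slope -0.198 without BC array 4. The RMG slope was 0.0908 without RMG array 10 and 0.0988, 0.0946 and 0.0958 without ND array 6, ND array 8 and HFD array 4. The SMG slope was 0.098 without SMG array 12, -0.24 without SMG array 5, -0.155 without SMG array 8, -0.161 without HFD array 4 and -0.0232 without HFD array 6.

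**Figure D3:**
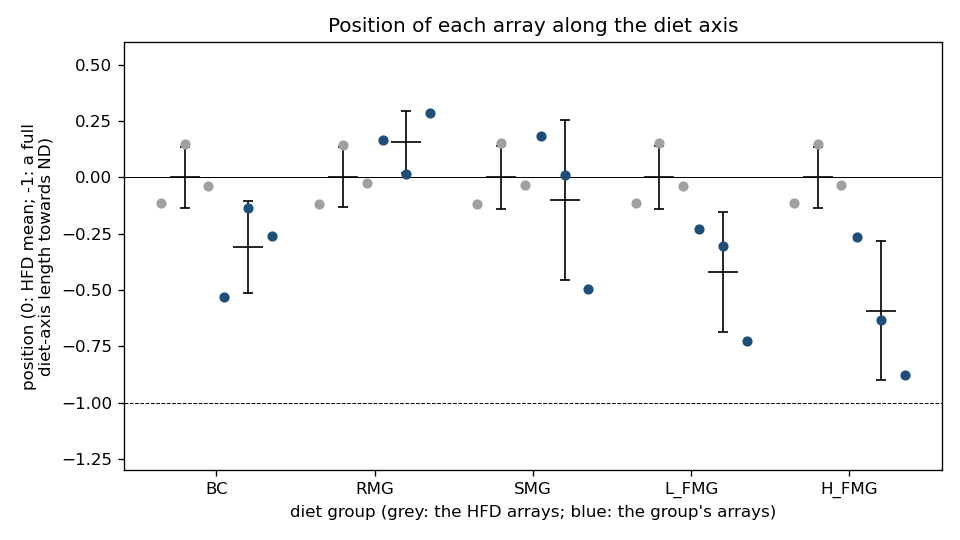
Position of each array along the diet axis (vertical axis, 0 is the HFD mean and -1 a full axis length towards ND) for each supplemented group (horizontal axis). The diet axis differs for each group. Blue points are the group's arrays, grey points the HFD arrays, marks are means and bars are SDs of 3 arrays. H_FMG arrays lay at -0.27, -0.64 and -0.88, and SMG arrays at 0.19, 0.01 and -0.50.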

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

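The 3 tests of explanations for the gene lists in H_FMG were chosen after the result was seen, and the splits of the arrays were planned.

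Between the 2 doses of fermented grain, H_FMG against L_FMG, 8 lists differed directly, interferon and macrophage genes among them. Between L_FMG and the other additions at 0.3%, 8 lists differed against SMG and 7 lists against BC, with cell cycle and cholesterol synthesis genes lower in both. These are differences between groups tested directly, and none of them held with an estimated correlation. Among 7224 probes without a single gene symbol, which the gene tests did not use, 158 differed between HFD and ND, 80 higher and 78 lower in HFD.

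Macrophage genes stood at -0.80 and endothelial genes at 0.40 in H_FMG against HFD, and 3 technical or compositional explanations were weighed for these shifts. A compression of the array values would also have lowered the bright adipocyte list. Without further normalization that list stood 0.262, 0.401 and 0.468 above the HFD mean in the H_FMG arrays. After quantile normalization, which itself evens out compression, it stood at 0.444 (SD of the HFD arrays 0.177). A larger share of adipocytes diluting every other cell type would have lowered the endothelial list, which stood at 0.4, against an SD of 0.152. Both directions were known when these tests were chosen, so they are not independent tests. A part played by either explanation is not excluded. HFD arrays standing high stay open. The macrophage list in H_FMG differed from the mean of the other 4 supplemented groups by -0.588, less than 2 SDs of their 12 arrays (SD 0.385). The difference was -0.842 against RMG and SMG together (SD of their arrays 0.334), -1 against RMG (SD 0.0844) and -0.683 against SMG (SD 0.443). It was -0.401 against BC (SD 0.287) and -0.267 against L_FMG (SD 0.227). A lower share of macrophages also stays open: 12 of 13 markers were lower, but that count was set aside as a test, after it had been seen, because the list was picked for being lower, and without H_FMG array 8 the macrophage change was -0.579. An effect of the fermented grain on these lists may be one explanation, and mouse-to-mouse differences in the make-up of the fat pad another. Another split of the same 6 arrays gave 15 lists, as many as the real one. Each such split mixes arrays of both groups, so a group effect enters it in part, and the count cannot tell these explanations apart.

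For comparisons of 3 against 3 arrays there are 10 splits, too few for a share under 0.05, so only the real count and the highest count of another split are given. In HFD against ND 1 of 10 splits, the real one, gave 1403 genes, and the highest other gave 3; for lists 4 of 10 gave at least the real 12, with up to 17 in another split. In H_FMG against HFD 2 of 10 splits gave at least the real 1 gene, with 1 in the other, and 2 of 10 gave at least 15 lists, with 15 in the other. In L_FMG against HFD all 10 gave at least the real 0 genes (highest other 0), and 1 gave at least 9 lists (highest other 7). In BC all 10 gave at least 0 genes (highest other 0), and 5 gave at least 5 lists (highest other 8). In RMG all 10 gave at least 0 genes (highest other 0), and 1 gave at least 14 lists (highest other 10). In SMG all 10 gave at least 0 genes (highest other 0) and at least 0 lists (highest other 15). Between the doses all 10 gave at least 0 genes (highest other 0), and 3 gave at least 8 lists (highest other 15). In L_FMG against SMG all 10 gave at least 0 genes (highest other 1), and 4 gave at least 8 lists (highest other 14), and in L_FMG against BC all 10 gave at least 0 genes (highest other 1), and 2 gave at least 7 lists (highest other 9).

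Of 100 drawn splits, 7 gave at least the real 15 lists for the dose trend (highest other 18), 50 at least the real 5 lists for the pooled comparison (highest other 17), and 6 at least the real 8 genes among the 6 high-fat groups (highest other 1108), so chance is not excluded for these. All 100 gave at least the real 0 genes for the trend (highest other 878) and for the pooled comparison (highest other 2). Splits with 878 and 1108 genes, far above the real 0 and 8, may point to a structure of the samples, which was not tested further.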

How the results depend on the processing

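The fits without ND array 9 of comparisons that hold no ND array, and list tests after quantile normalization, were chosen after the data were seen.

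Of the main results across settings, 431 kept their side of the threshold or a count within 1.5 times, 46 gained, 56 lost and 1 reversed. Of single genes and lists 9660 were unchanged, 141 gained, 481 lost and 27 reversed. A count that stayed at 0 and a gene left uncalled in both fits are among those kept, and slopes were scored by sign alone. These totals therefore do not measure how well calls held. In HFD against ND, 27 of the 55 named calls were lost in some fit with 1 array left out. The number of arrays limits small changes: 38.8 percent of simulated changes of 0.5 log2 units were recovered in HFD against ND, and signal over background was not used here. The cause was not tested where a result changed, except that fewer arrays or genes enter some settings. Genes in HFD against ND numbered 774 with those arrays alone, 2432 with array weights, 2476 at an adjusted p of 0.1 and 368 to 1457 with 1 array left out. Genes in H_FMG against HFD numbered 0 with every probe, 566 with weights, 44 at 0.1 and 0 to 257 with 1 array left out. In L_FMG they were 3 with its own arrays and HFD alone, 1 with weights and 1 at 0.1. With weights there were 2 in RMG, 15 in L_FMG against SMG and 1 in L_FMG against BC. With 1 array left out the range was 0 to 1 in SMG and in L_FMG against BC. The dose trend gave 1 after quantile normalization, 2 with dim genes left out, 222 with weights, 1 at 0.1 and 0 to 89 with 1 array left out. The test among the 6 high-fat groups gave 0 without a variance trend, 16 with its own arrays, 56 after quantile normalization, 63 with dim genes left out, 4 with every probe, 1436 with weights, 223 at 0.1 and 0 to 657 with 1 array left out.

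Lists numbered 0 with an estimated correlation in all 10 comparisons that had calls, and 7 by fry in HFD against ND and 0 in the other 9. With weights they numbered 19 in HFD against ND and 1 in SMG. In BC they numbered 9 after quantile normalization and 9 with dim genes left out, and in the pooled comparison 3 with dim genes left out. With 1 array left out they ran from 5 to 9 in BC, 9 to 16 in RMG, 0 to 5 in SMG, 4 to 13 between the doses, 4 to 11 in L_FMG against SMG and 3 to 8 in the pooled comparison. The SMG slope ran from -0.244 to 0.0979. Reversed values of uncalled genes in HFD against ND were Sfrp5 -0.041, Elovl6 -0.116 and Il6 0.077 after quantile normalization and Mest -0.004 and Elovl6 -0.263 with weights. With 1 array left out the ranges were Mest -0.069 to 0.284, Sfrp5 -0.033 to 0.263, Ppargc1a -0.13 to 0.125, Elovl6 -0.356 to 0.235 and Il6 -0.133 to 0.11, in RMG Lcn9 -0.065 to 0.472 and Emcn -0.211 to 0.01, and in L_FMG against SMG Krt18 -0.061 to 0.638 and Adipoq -0.029 to 0.396.

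With the mouse number as a replicate block the counts of genes were 524 in HFD against ND, 26 in H_FMG, 15 for the trend and 140 among the high-fat groups, and of lists 11 in BC, 7 in RMG, 3 in SMG, 5 in L_FMG and 15 between the doses. Reversed values with the block were Ppargc1a -0.288 and Elovl6 -0.006 in HFD against ND, Foxo1 0.037, Emcn 0.019, Tek 0.05, Cpt2 0.07, Mgll 0, Myh11 0, Rgs5 0.011 and the fatty acid oxidation list 0.0314 in RMG, Prkar2b -0.037 in L_FMG, and Msln -0.321 and the mesothelial list -0.167 in L_FMG against SMG. The numbers are not shown to pair the mice: deviations of 18 same-numbered pairs had a median correlation of -0.0463 (from -0.302 to 0.178, 2 pairs over 0.1), against -0.00489 for other pairs.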

Other observations

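The test of ND array 9 as a mouse of a high-fat group was chosen after its result was seen, and the other tests were planned before their results.

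Several cell types of the fat pad did not pass in HFD against ND. Thermogenic genes, such as Cidea and Prdm16, had a mean change of 0.07 (adjusted p = 0.999), T cell markers of -0.15 (adjusted p = 0.328), B cell markers of -0.115 (adjusted p = 0.567) and neutrophil markers of 0.10 (adjusted p = 0.731). Mast cell genes had a mean change of 0.59 (adjusted p = 0.105), and their level in single arrays ran from -0.413 to 0.313 around the mean in HFD and from -0.803 to -0.403 in H_FMG. Mesothelial markers varied as much within groups as between them: they stood at 0.578, -0.226 and -0.389 in the ND arrays, at 0.546, -0.274 and -0.272 in the HFD arrays and at 0.37, -0.285 and 0.435 in the L_FMG arrays.

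ND array 9 stood apart from the other ND arrays, with an array weight of 0.208 and the lowest mean correlation with the other arrays (0.972). Lipogenesis genes stood at -0.222 against the HFD mean in it and at 0.336 and 0.332 in ND arrays 6 and 8, and branched-chain amino acid genes at -0.315 against 0.494 and 0.467. In other lists ND array 9 stood with its group. The matrix list was at -0.448 (-0.468 and -0.415 in ND arrays 6 and 8) and the cell cycle list at -0.538 (-0.601 and -0.608). These 2 lists do not tell it from every high-fat array, since H_FMG array 8 stood at -0.465 and -0.729 in them. Along the axis from ND arrays 6 and 8 to the supplemented groups ND array 9 lay at a slope of 0.339 (0.412 and 0.266 with either ND array setting the axis), the 3 HFD arrays at 0.707, 0.908 and 0.716, and the H_FMG arrays at 0.535, 0.328 and 0.129, so a mouse of a high-fat group stays open. A compression of its values would have shrunk the difference of the lipid-associated macrophage list after quantile normalization, whereas 115% of it remained (1.14 before and 1.31 after). For that list, which was higher in ND array 9, this argues against compression, and so against it as the whole cause. Lists lower in ND array 9, such as lipogenesis, were not tested this way. The array also had the lowest SD over probes (1.823), so compression stays open for them. No biological explanation was tested, and the cause stays open.

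Sperm genes stood higher in RMG array 9 than in any other array: Tnp2 at 5.59 against 4.33 in the next highest, Smcp at 4.47 against 3.43 and Prm1 at 5.45 against 4.77, and 5 of 6 measured testis genes had their highest value there. The fifth of these, the Odf1 probe, read 11.34 in the median of the other arrays too. Testis or sperm RNA carried over with the fat may be one explanation: in a second list of sperm genes 7 of 26, or 26.9%, had their highest value on RMG array 9, against 4.76% by chance and 5 genes on the next array, which lies between the bounds set for and against it and leaves it open. Values raised across the whole array are argued against, since 6.53% of all genes had their highest value on it.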
